A study of Mus musculus with 4 samples.

How the data were processed

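RNA from 4 mouse CD4+ T cell samples was hybridised to 1-colour Agilent mouse expression arrays with Cy3, 1 array per group. Per the labels' protocols, CD4 T cells of BALB/c spleen and lymph nodes were parted into CD25+ and CD25- cells with magnetic beads and then sorted. Naive T cells (CD4+CD25-CD62L-high) and natural regulatory T cells (Treg, CD4+CD25+) were taken without transduction. The other 2 samples were Treg transduced with a lentivirus that carried a short hairpin RNA and a GFP reporter, kept for 60 h with human IL-2 and sorted for GFP. One hairpin was directed at Eos (si-Eos) and the other at Renilla luciferase (si-RL), the control. RNA was extracted with Trizol and amplified linearly before labelling, per the labels' protocols.

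The deposited scanner files held spot intensity values on a linear scale, made with Agilent Feature Extraction 9.5.3.1 per the file headers. The processed intensity was background-subtracted by spatial detrending and was not normalized between arrays, per the file headers. The headers place the probes on mouse build mm8, and all 4 arrays were on 1 slide in 1 scan, so slide and scan could not separate the groups. The series value table held the processed intensity of the same spots, as deposited by the authors: the median ratio to the scanner value was 1.00 on every array, and 100% of spots agreed within 0.5%. Its column medians were 33.2 for naive T, 50.5 for Treg, 38.5 for the library labelled si-Eos and 31.5 for the library labelled si-RL. It was linear and not centred.

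From these files, log2 of the processed signal minus each array's 75th percentile over the 41174 non-control probes was computed. Spots flagged as non-uniform or population outliers were left out (71 to 94 of 43379 spots per array), and spots of 1 probe were averaged on the log2 scale. No non-control spot was saturated. Names came from the accession of a RefSeq table of mouse assembly GRCm38.p6 for 24375 probes, from a current symbol for 6301 and from a single synonym for 2426, and 8072 probes kept the name in the file. Each of the 27593 genes was represented by its brightest probe, the one with the highest mean level over the 4 arrays. A gene counted as measured in a comparison where its probe was well above background on both arrays. Where no probe of a gene was well above background on 1 of the arrays, the difference was given as "at least N-fold", the bright array's level over the higher of the lowest level well above background on the dim array and the dim probe's own level.

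With 1 array per group there was no spread between replicates, so no test was run and no p-value is given. Genes were counted where 2 arrays differed by at least 2-fold. The ± beside a log2 difference is the scanner software's error estimate of the 2 spots combined, a technical error only. It leaves out disagreement between probes of 1 gene. The median gap between another probe and the probe used was 0.17 for Treg against naive T and 0.41 between the hairpin libraries. For the libraries labelled si-RL and si-Eos against Treg it was 0.39 and 0.31. The median log2 error per spot was 0.15 on every array, and the median SD of replicate spots of 1 probe was between 0.07 and 0.09. The number of arrays, not the number of spots, limits the precision.

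Before the data were examined, 27 gene lists with 603 entries were fixed, of which 593 were found on the array, together with the comparisons, the alternatives and the rule for naming genes. For each list with at least 5 measured genes, the median log2 difference was set against 10000 random lists of the same size matched on mean level in 20 bins. The list of erythrocyte and platelet markers had under 5 measured genes and gave no median. The rule named, per comparison, Eos and Foxp3, the 12 largest differences each way among genes with a plain symbol whose other measured probes went the same way, up to 4 members of each list that were at least 2-fold apart, and up to 5 genes each way that were above background on 1 array only. Not all of them are named in the text.

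The counting step was tested on simulated differences made from the scanner errors of the measured genes. The list step was tested on the observed differences shuffled over genes. Of 50 genes planted with a 3-fold difference, 49 were counted in the right direction for Treg against naive T (17595 genes), 50 for the 2 hairpin libraries (17082 genes) and 50 for the library labelled si-RL against Treg (17082 genes). Unchanged genes were counted 8 times in 17395, 11 times in 16882 and 15 times in 16882. This simulation held scanner error only, without the spread between samples, amplifications or probes of 1 gene. Such low counts of unchanged genes were bound to follow, and they give no false rate for the real counts. Of 100 lists of 30 genes shifted by 0.5 on the log2 scale, 100, 85 and 99 lay above the middle 95% of random lists in the same 3 comparisons, so the list step was least sensitive between the hairpin libraries. Of 100 unshifted lists, 6, 10 and 3 lay outside it. Their members were taken at random and the differences shuffled, so these numbers do not hold for real lists whose genes vary together.

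The 11 alternatives fixed before the data were examined were normexp background correction (offset 50), scaling to the median, quantile normalization, the 75th percentile of probes detected on all arrays, the deposited table, no filter on dim probes with a floor, a filter 4 times stricter, the median of a gene's probes, removal of a loess trend (span 0.4), and thresholds of 3-fold and 1.5-fold. After the data had been seen, 2 more were added, scaling to 7 spike-in probes and normexp with 1 background value per array, as was a comparison of the library labelled si-Eos against Treg. R 4.3.3 with limma 3.58.1 ran normexp. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 did the rest.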

Results

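The series measured mRNA levels in 4 CD4+ T cell samples of BALB/c mice: naive T cells, untransduced regulatory T cells (Treg) and 2 samples of Treg transduced with a hairpin RNA, 1 labelled si-Eos and 1 labelled si-RL, the Renilla luciferase control. Eos is the zinc-finger protein encoded by Ikzf4, and Foxp3 is the transcription factor that defines Treg. Each group was 1 array, so there were no replicates. Every difference below compares 2 libraries and has no replicate check. Of 41174 probes, 26721 (64.9%) were well above background in naive T cells, 27900 (67.8%) in Treg, 28112 (68.3%) in the library labelled si-Eos and 26354 (64.0%) in the library labelled si-RL. The 75th percentile of the processed signal was 303 in naive T, 392 in Treg, 320 in the library labelled si-Eos and 262 in the library labelled si-RL.

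The targeted gene was examined first, since the question of the series, from its title, was whether Eos takes part in gene silencing by Foxp3. Eos mRNA was higher in the library labelled si-Eos than in the library labelled si-RL on all 3 Ikzf4 probes, which goes against the labels. The probes lie on chromosome 10 (mm8), and which exon or UTR they fall in was not analysed here. The brightest (128036782 to 128036841) differed by 0.93 ± 0.21 on the log2 scale, or 1.90-fold. The second (128036473 to 128036532) differed by 1.96 ± 0.21 and the third (128037711 to 128038748) by 1.19 ± 0.22. Against untransduced Treg, the library labelled si-RL read lower on all 3 probes, by log2 differences of -1.18 ± 0.21, -1.27 ± 0.21 and -0.67 ± 0.22 in the same order. The library labelled si-Eos differed from Treg by -0.25 ± 0.20, 0.69 ± 0.20 and 0.52 ± 0.21. Treg exceeded naive T cells by 0.54 ± 0.20, 2.67 ± 0.22 and 0.61 ± 0.21.

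Foxp3 was also higher in the library labelled si-Eos than in the library labelled si-RL. Its probe (chromosome X, 6751991 to 6752050, mm8) had a processed signal of 64.4 in naive T cells, 1778 in Treg, 2644 in the library labelled si-Eos and 110 in the library labelled si-RL. Foxp3 was 21.3-fold higher in Treg than in naive T cells and 19.7-fold higher in the library labelled si-Eos than in the library labelled si-RL. Because the targeted gene contradicts the labels, each direction below between the hairpin libraries holds for the libraries as labelled. If the labels were exchanged, every such sign would turn.

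**Figure D1:**
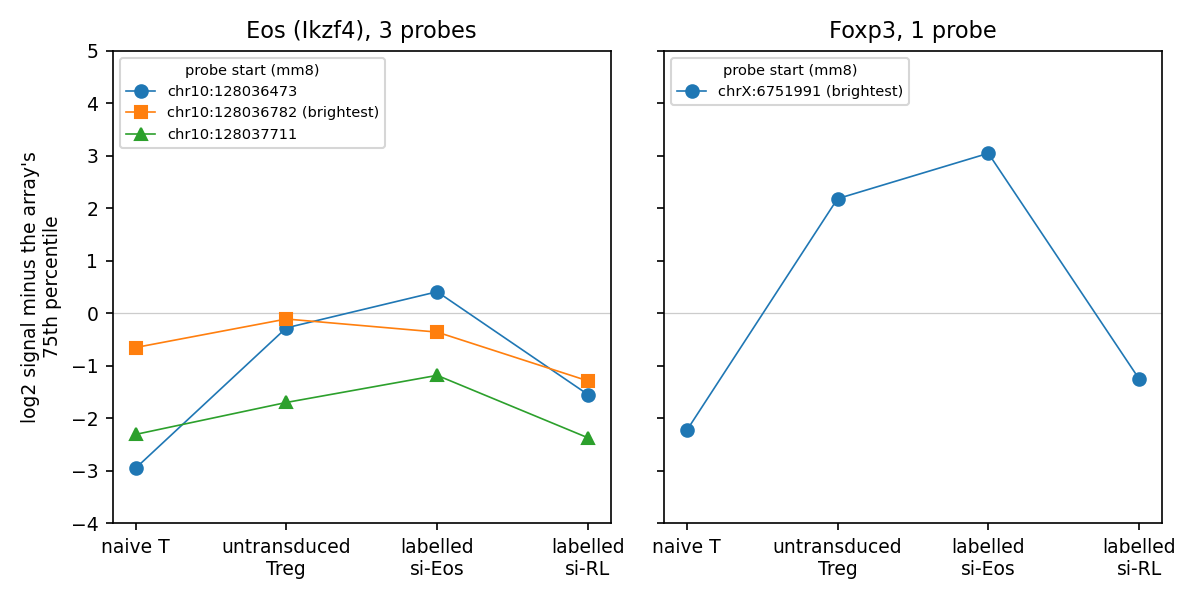
Level of each Eos probe (left, 3 probes) and of the Foxp3 probe (right) on the 4 arrays, as log2 signal minus the array's 75th percentile; each point is 1 array, lines join points of 1 probe, and the groups have no order. All 3 Eos probes lie lower in the library labelled si-RL than in the library labelled si-Eos, by 0.93 to 1.96, and Foxp3 lies 4.30 lower there.

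The comparison of untransduced Treg with naive T cells sets out which genes differ between these 2 samples. Naive T cells were sorted as CD62L-high, and the labels name no such gate for Treg. Genes of Treg identity therefore cannot be told apart here from genes of an activated against a naive state. Of the 32 measured genes of the Treg signature list, 28 were at least 2-fold higher in Treg, with a list median of 3.17. Among them were Penk (proenkephalin, 6.57 ± 0.21), Itgae (integrin αE, CD103, 5.36 ± 0.21), Il2ra (the IL-2 receptor α chain, CD25, on which the cells were selected, 5.33 ± 0.23) and Ikzf2 (Helios, 4.53 ± 0.20). Suppressive effector genes were also higher, 9 of 14 by at least 2-fold, among them Ctla4 (3.65 ± 0.20), Lag3 (4.07 ± 0.28) and Ebi3, a subunit of IL-35 (4.41 ± 0.21). In the list of genes known to be low in Treg, 14 of 24 were at least 2-fold lower, including Dapl1 (-4.03 ± 0.20), Igfbp4 (-3.30 ± 0.21) and Pde3b, a phosphodiesterase (-2.94 ± 0.21). That list also held 4 genes that were at least 2-fold higher, and Ifng (interferon-γ) was one, at 2.86 ± 0.20. The transcription factor Lef1, of the naive and quiescence list, was lower by a log2 difference of -2.14 ± 0.20, and 11 of that list's 24 genes were at least 2-fold lower. Pdlim4 (-4.27 ± 0.20) was among the largest negative differences, with -2.26 on its other measured probe.

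Cell cycle genes were higher in Treg: 24 of 26 M-phase genes and 14 of 24 S-phase genes by at least 2-fold, with medians of 2.18 and 1.29. Aurkb (aurora kinase B) differed by 2.83 ± 0.24 and Rrm2 (ribonucleotide reductase M2) by 2.72 ± 0.21. Activation genes were at least 2-fold higher in 14 of 24, such as Tnfrsf9 (4-1BB, 4.06 ± 0.21). IL-2 and STAT5 target genes were so in 9 of 20, with Socs2 at 4.76 ± 0.21. Of chemokine receptor and adhesion genes, 13 of 28 were at least 2-fold higher and 3 lower, with Ccr6 at 3.42 ± 0.20 and Cxcr3 at 3.05 ± 0.20. Effector cytokine genes had a median of 0.73, above all random lists, with 7 of 15 at least 2-fold higher and 2 lower. All 30 ribosomal protein genes were lower, none by 2-fold, with a median of -0.61. B cell markers were higher too, 5 of 12 by at least 2-fold, with H2-Aa at 2.70 ± 0.24 and Cd79b at 1.88 ± 0.20. Cholesterol synthesis genes (median -0.02) and oxidative phosphorylation genes (median -0.08) lay inside the middle 95% of random lists.

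Of 17595 measured genes, 970 (5.51%) were at least 2-fold higher in Treg and 359 (2.04%) were at least 2-fold lower. Slc7a10, an amino acid transporter, and Il1r2, the decoy IL-1 receptor, were well above background in Treg alone, at least 58.2-fold and at least 43.8-fold higher. The share of higher genes among those 2-fold apart, 73.0%, moved to 55.2% when arrays were scaled to their medians and to 88.1% with spike-in scaling. With the main scaling, 382 of the genes apart had another measured probe, and for 21 (5.5%) of these a probe went the opposite way.

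The 2 hairpin libraries were then compared, to ask what differed when the Eos hairpin took the place of the control hairpin. The library labelled si-Eos carried the higher level of Treg genes. Of 29 measured Treg signature genes, 23 were at least 2-fold higher there and none was 2-fold lower (median 2.58). Penk was higher by 9.24 ± 0.21, Itgae by 6.75 ± 0.24 and Ikzf2 by 3.59 ± 0.20. Suppressive effector genes were at least 2-fold higher in 9 of 12, including the cytolytic protease gene Gzmb (3.89 ± 0.20) and Entpd1 (CD39, 3.42 ± 0.22). Lag3 and Il10 were well above background in the library labelled si-Eos and not in the library labelled si-RL, and were at least 181-fold and at least 158-fold higher. The chemokine genes Ccl3 (10.23 ± 0.32) and Ccl4 (9.26 ± 0.24) and Spp1 (osteopontin, 10.08 ± 0.24) were among the largest differences. Their signals in naive T cells, Treg and the library labelled si-RL were all below 80.

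Genes of naive and quiescent T cells were higher in the library labelled si-RL. Of the 24 measured, 12 were at least 2-fold lower in the library labelled si-Eos and 1 was higher, with a median at percentile 0 of random lists. S1pr1, the receptor for lymphoid egress, differed by -6.41 ± 0.21, the transcription factor gene Tcf7 by -4.53 ± 0.20 and Dapl1 by -4.91 ± 0.22. Pdlim4 (-6.68 ± 0.21), Drc1 (-6.66 ± 0.21) and Pde3b (-5.28 ± 0.21) were also among the largest. The other measured probe of Pdlim4 differed by only -1.82. Signals of S1pr1 were 4471 in naive T cells, 2203 in Treg, 51.7 in the library labelled si-Eos and 3600 in the library labelled si-RL. The list of genes known to be low in Treg had 14 of 23 members at least 2-fold lower in the library labelled si-Eos. From that list, Ifng (4.78 ± 0.21) and Ly6c1 (6.25 ± 0.21, and 1.60 on its other measured probe) were higher. Activation genes were at least 2-fold higher in 16 of 22, with Pdcd1 (PD-1) at 5.11 ± 0.21 and Tnfrsf9 at 4.56 ± 0.20.

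Metabolic and stress genes separated the libraries as well. Cholesterol synthesis genes were at least 2-fold higher in the library labelled si-Eos in 16 of 21 (median 1.74), with Fdps (farnesyl diphosphate synthase) at 2.47 ± 0.20 and Idi1 at 2.31 ± 0.20. For Nsdhl, from the same list, the probes went both ways. Stress genes of the endoplasmic reticulum and amino acid response were so in 15 of 23 (median 1.51), with Atf3 at 3.45 ± 0.21 and Asns (asparagine synthetase) 8.59-fold higher. Oxidative phosphorylation genes had a median of 0.71 and 25 of 27 were higher, 6 of them by 2-fold. S-phase genes had a median of 0.91, with Mcm5 at 2.35 ± 0.20. M-phase genes had a median of 0.25, inside the middle 95% of random lists. Glycolysis genes had a median of -0.36, below the middle 95% of random lists (-0.22 to 0.49). Pdk1 (pyruvate dehydrogenase kinase 1), from this list, differed by -3.66 ± 0.20. Medians of the p53 and apoptosis list (-0.06), B cell markers (0.26) and myeloid markers (0.46) lay inside the middle 95% of random lists, though the B cell marker Cd74 differed by 2.54 ± 0.23.

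Of 17082 measured genes, 1829 (10.7%) were at least 2-fold higher in the library labelled si-Eos and 1724 (10.1%) were lower. Eos was higher there, against the label, and so was Foxp3. With normexp background correction and 1 background value per array, the counts were 1149 and 829. With the main scaling, 1107 of the genes apart had another measured probe, and for 197 (17.8%) of these a probe went the opposite way.

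To ask whether genes that are low in Treg were higher after the Eos hairpin, genes were taken from the Treg and naive T arrays and followed in the hairpin libraries, which share no array with them. The 295 genes at least 2-fold lower in Treg than in naive T cells had a median difference of -1.17 between the library labelled si-Eos and the library labelled si-RL, below all 10000 random lists, whose middle 95% ran from -0.07 to 0.13. Of them, 162 were at least 2-fold lower in the library labelled si-Eos and 12 were higher. The 900 genes at least 2-fold higher in Treg had a median of 0.85, above all random lists (middle 95%, -0.01 to 0.10), with 392 at least 2-fold higher and 47 lower. As labelled, then, Treg-lower genes were lower and Treg-higher genes higher in the Eos hairpin library. With the labels exchanged, the medians would be 1.17 and -0.85. Over 16449 genes measured on all arrays, the 2 differences correlated across genes with Pearson's r = 0.38 and Spearman's rho = 0.24, and genes are not independent replicates. The sign of r would turn with the labels. Under normexp with local backgrounds, the remade Treg-higher list had a median of -0.0916, still above all random lists there, the remade Treg-lower list had -0.42 and r was 0.13.

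**Figure D2:**
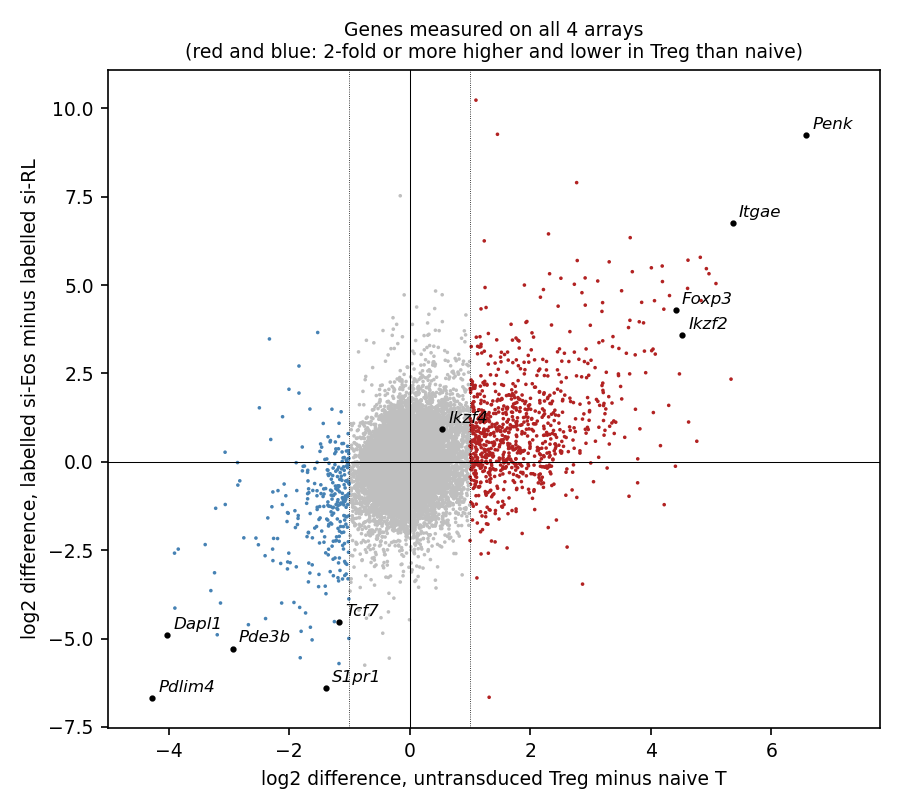
Each point is 1 of 16449 genes measured on all 4 arrays; the horizontal axis is the log2 difference of untransduced Treg minus naive T and the vertical axis that of the library labelled si-Eos minus the library labelled si-RL. Genes at least 2-fold higher in Treg (red, 900 genes) lie mostly above 0 and genes at least 2-fold lower (blue, 295 genes) mostly below 0, with medians of 0.85 and -1.17.

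The library labelled si-RL, by its label the control hairpin, was set against untransduced Treg. If the label holds, the differences go with transduction, 60 h of culture and the GFP sort. If the labels were exchanged, this library would carry the Eos hairpin as well, and the library labelled si-Eos would be the control. The library labelled si-RL had lower levels of Treg genes: 18 of 29 Treg signature genes were at least 2-fold lower, such as Penk (-7.35 ± 0.21), Itgae (-6.59 ± 0.24), Ikzf2 (-3.95 ± 0.20) and Foxp3 (-3.43 ± 0.21), and 2 were higher, of which Gzmb was one (3.99 ± 0.21). Suppressive effector genes were at least 2-fold lower in 8 of 12, including Entpd1 (-3.34 ± 0.22) and Nt5e (CD73, -2.98 ± 0.21). Of naive and quiescence genes, 8 of 24 were at least 2-fold higher, such as Lef1 (2.37 ± 0.20), and 1 lower, with a list median of 0.20 inside the middle 95% of random lists. Glycolysis genes were at least 2-fold higher in 15 of 18 (median 2.04), with the lactate transporter gene Slc16a3 at 4.42 ± 0.20 and Hk2 (hexokinase 2) at 3.72 ± 0.20. Of the p53 and apoptosis list, 12 of 24 were at least 2-fold higher, led by Cdkn1a (p21, 6.95 ± 0.32) and Phlda3 (6.29 ± 0.20). Vegfa was higher by 6.18 ± 0.21.

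Interferon-stimulated genes were lower in the library labelled si-RL, 16 of 31 by at least 2-fold (median -1.03), including Usp18 (-3.50 ± 0.21) and Ifit3 (-3.30 ± 0.22). Immediate early genes had a median of -0.90, with Dusp1 at -2.43 ± 0.20. Heat shock genes had a median of -0.69, with Hspa1a at -3.27 ± 0.21. Pan-T and T cell receptor signalling genes had a median of -0.44, with Cd5 at -1.76 ± 0.20. B cell markers were lower, 5 of 11 by at least 2-fold, and Jchain, the immunoglobulin joining chain, was lower by a log2 difference of -8.33 ± 0.26. M-phase genes had a median of 0.59 and S-phase genes one of -0.50. Of 17082 measured genes, 1348 (7.89%) were at least 2-fold higher and 1402 (8.21%) were lower. With spike-in scaling, these counts were 613 and 3188, so the balance of higher and lower genes rests on the scaling. With the main scaling, 847 of the genes apart had another measured probe, and for 163 (19.2%) of these a probe went the opposite way.

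The library labelled si-Eos was also set against Treg, a comparison added after the Eos values were seen. It had 1583 genes at least 2-fold higher and 1796 lower, of 17897. Glycolysis genes were at least 2-fold higher in 14 of 18 (median 1.74), and Cdkn1a (7.56 ± 0.32) and Phlda3 (5.49 ± 0.20) were higher here too, while interferon-stimulated genes had a median of -0.77. Both hairpin libraries were compared with the same Treg array, so likeness between these 2 comparisons comes in part from that array. Unlike in the library labelled si-RL, Treg signature genes were higher than in Treg, 13 of 33 by at least 2-fold, and 4 were lower (median 0.83). Gzmb was higher by 7.88 ± 0.21, and so were 5 of 9 measured NK and CD8 T cell markers by at least 2-fold (median 1.73, above all random lists). Of naive and quiescence genes, 9 of 24 were at least 2-fold lower, such as S1pr1 (-5.12 ± 0.21), and 3 higher (median -0.64). With spike-in scaling, the counts were 900 and 2874. With the main scaling, 960 of the genes apart had another measured probe, and for 139 (14.5%) of these a probe went the opposite way.

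**Figure D3:**
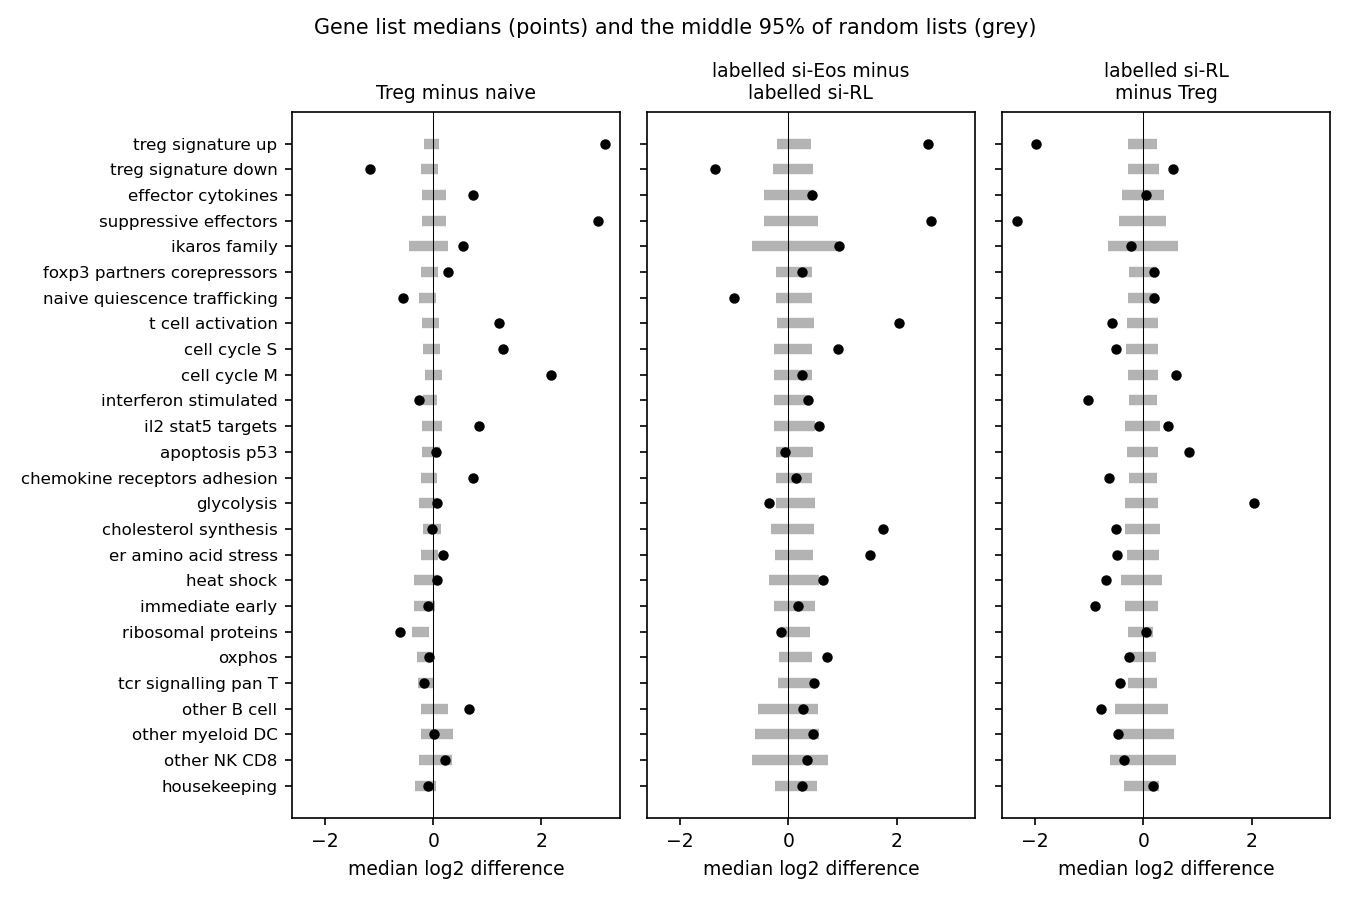
Points are the median log2 difference of each gene list fixed before the data were examined, in 3 comparisons, and grey bars the middle 95% of 10000 random lists matched on level. The Treg signature list lies at 3.17 in Treg minus naive, at 2.58 in the library labelled si-Eos minus the library labelled si-RL and at -1.99 in the library labelled si-RL minus Treg.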

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

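In this part, the tests of scaling, of exchanged labels, of intensity and background, and of mixed naive T cells were chosen after the results were seen. The test of Eos against other Treg genes was set before its value was seen.

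The 2 hairpin libraries differed from untransduced Treg in opposite directions for some genes, a difference between groups that was not tested. At least 2-fold above Treg in the library labelled si-Eos and at least 2-fold below it in the library labelled si-RL were 107 of 16795 measured genes, with Ccl3, Penk, Ly6a and Zbtb32 among the widest gaps. The reverse held for 54 genes, among them Pdlim4, Drc1 and S1pr1. Independent lists of these sizes would share 119 and 127 genes, more than the 107 and 54 seen. Simulated unchanged libraries against the same Treg array shared 0 in each direction. That simulation could hold no spread between replicate libraries, since none was measured, so its 0 does not show that these genes differ. Foxp3 was above Treg by 0.87 in the library labelled si-Eos and below it in the library labelled si-RL, with a log2 difference of -3.43.

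Eos mRNA was higher in the library labelled si-Eos than in the library labelled si-RL. Scaling between arrays is argued against, since the lowest difference over 3 probes and 6 scalings or background corrections was 0.61. Exchanged labels of the hairpin libraries may be the cause: all 3 probes read below Treg in the library labelled si-RL, by at least as much as a log2 difference of -0.67, and 2 of 3 read above Treg in the library labelled si-Eos. Eos may instead be low along with other Treg genes there. Its difference from Treg in the library labelled si-RL lay at percentile 30.1 of those of 900 Treg-higher genes. Those genes were chosen for high levels on the same Treg array, which by itself pushes their differences down. The Eos probe used was only 0.54 higher in Treg than in naive T cells, short of the 2-fold of that list. The percentile therefore could not decide. Both stay open, as does an effect of the hairpins themselves, and the files give no sequence or second measurement that would separate them.

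Treg-higher genes were low and Treg-lower genes high in the library labelled si-RL relative to the library labelled si-Eos. An intensity trend, the background correction or quantile scaling is argued against as the whole cause. Over 7 other settings, the genes of both lists kept a median shift of at least 0.52 in size. Loess, quantile scaling and both normexp settings left these shifts outside random lists. Scaling to the median, to detected probes or to spike-ins moves a list and its random lists alike, so this test could not decide on such scaling. An earlier form of this test, with lists remade under each setting, gave -0.0916 for Treg-higher genes under normexp with local backgrounds, and was replaced by the genes of the main lists after that value was seen. A mix of naive T cells and Treg that both kept their fresh levels would not give these values. The Foxp3 level would need 95.2% naive T cells, which would leave Treg-lower genes at a median of -0.0417 from naive T. These genes read -0.84, and -0.62 or lower under 6 scalings. The library had been kept for 60 h, however, and culture could lower genes in any cells, so naive T cells that changed in culture stay open. Culture could also lift genes in any cells, so 2 earlier tests of this decided nothing. In them, 17 of 295 Treg-lower genes were at least 2-fold above both fresh samples and 20.1% of Treg-higher genes were at least 0.4 above Treg. Conventional T cells changed by transduction and culture could account for the pattern, although the labels name CD4+CD25+ cells and the CD25 selection would remove most of them. With 0 arrays of such cells, this cannot be told apart from an effect of a hairpin on Treg.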

How the results depend on the processing

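Spike-in scaling, normexp with 1 background value per array, the other Eos probes and the comparison of the library labelled si-Eos with Treg were chosen after seeing the data. Across the alternatives, 182 main counts, medians and levels moved little, 66 moved and 1 reversed, while 961 list medians moved little, 175 moved and 5 reversed, and 3094 values of named genes moved little, 972 moved and 13 reversed. A list counted as reversed only where its main median was at least 0.5 of the width of the random middle 95% from 0, and a gene only where it was at least 2-fold apart, so medians near 0 that changed sign are not among these. No count of gene lists outside random lists moved by over 1.5 times. Quantile scaling and loess moved no gene count by over 1.5 times. Nor did the deposited table, but it held the same intensities, so its values could hardly move, and they are part of these tallies. Scaling to the median, to detected probes or to spike-ins could not change r, since it shifts whole arrays. No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. Dim probes limit the counts: signal over background set which genes were measured.

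Normexp with local backgrounds gave the only reversal of a main result. On the Treg array 7 spots had a local background over 2 times the median, up to 23686, and on the naive T array 6 did. Replacing local backgrounds by 1 value per array removed the reversal, with a Treg-higher median of 0.80. Under normexp with local backgrounds, genes at least 2-fold apart, higher and lower were 2259, 1887 and (little moved) 372 for Treg against naive T, 1969, 1138 and 831 between the hairpin libraries, 5423 apart and 4462 lower for the library labelled si-RL against Treg, and 7303 apart and 5857 lower for the library labelled si-Eos against Treg. The Treg-lower median was -0.42, the Treg-higher median reversed to -0.0916 but still lay above all random lists (middle 95%, -0.18 to -0.15), r was 0.13, and the Eos and Foxp3 differences between hairpin libraries were 0.66 and 3.63. The 899 Treg-higher genes of the main list that could be followed kept a median of 0.53. With 1 background per array, the counts were 717, 521 and 196, then 1978, 1149 and 829, then 1520, 716 and 804, then 1942, 936 and 1006. The Treg-lower median was -1.03, r was 0.41, and Eos and Foxp3 differed by 0.65 and 3.66.

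At 3-fold, the counts apart, higher and lower were 656, 544 and 112, then 1298, 692 and 606, then 1015, 443 and 572, then 1477, 620 and 857, as a higher threshold must give. The Treg-lower and Treg-higher medians were -1.82 and 1.10 at 3-fold and -0.48 and 0.49 at 1.5-fold. The stricter filter, which tests fewer genes, gave 837 apart and 587 higher for Treg against naive T, 920 lower for the library labelled si-RL against Treg and 1188 lower for the library labelled si-Eos against Treg. Median scaling gave 627 genes lower in Treg than naive T and medians of -0.79 and 0.95. Spike-in scaling gave 1471 higher and 198 lower for Treg against naive T, 613 and 3188 for the library labelled si-RL against Treg, 900 and 2874 for the library labelled si-Eos against Treg, and medians of -1.34 and 0.71. These scalings shift all genes: the median of all genes moved by -0.21 with median scaling and 0.28 with spike-in scaling for Treg against naive T, and by -0.41 and -0.34 with spike-in scaling for the libraries labelled si-RL and si-Eos against Treg. The share of higher genes among those apart then went from 49.0% to 16.1% and from 46.8% to 23.8%, and under normexp with local backgrounds to 17.7% and 19.8%, and to 83.5% for Treg against naive T. Quantile scaling gave a Treg-lower median of -1.04, the floor without a filter one of -0.80, and the 75th percentile of detected probes a Treg-higher median of 0.78. For Eos, the median of probes gave 1.19, and the other probes gave 1.96 and 1.19.

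Some lists and genes also reversed. For Treg against naive T, the shift of all genes by the scaling itself turned interferon-stimulated genes (median 0.0101) and pan-T genes (0.10) with spike-in scaling, and stress genes of the endoplasmic reticulum (-0.0317) with median scaling. The cause of the others was not tested. Those stress genes had -0.0833 with normexp. Oxidative phosphorylation genes had 0.23 with normexp for the library labelled si-RL against Treg. Under normexp, Cd40lg had 0.52 and Fosl2 0.59 for Treg against naive T. For the library labelled si-RL against Treg, Ccne2 had -0.87, Csf2 -1.17, Foxo3 -0.76 and Ier3 -0.87. For the library labelled si-Eos against Treg, Ccne2 had -0.78, Il22 -0.27, Csf2 -1.07, Ctbp2 -0.95, Itga2b -1.24 and Cd68 -0.13. Bcl2l1 had -0.20 between the hairpin libraries with the median of probes.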

Other observations

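In this part, the test of a single-spot artefact was chosen after the result was seen, and the test of islet markers was set on genes whose values had not been seen. Jchain and some immunoglobulin light chain transcripts were bright in both fresh samples and dim in both hairpin libraries. Jchain had a processed signal of 7008 in naive T cells and 8827 in Treg, against 18.4 in the library labelled si-RL, and was not well above background in the library labelled si-Eos. Iglv1 had 8066 and 9203 in the fresh samples, 34.0 in the library labelled si-Eos and 108 in the library labelled si-RL. The kappa gene Igkv4-55 had 2139 and 3095 in the fresh samples, then 61.8 and 25.0. Ighm, the μ heavy chain gene, had 1274 in the library labelled si-Eos and 3554 in the library labelled si-RL on the probe used. Its 3 probes ranged from -5.77 to -3.09 in the log2 difference of the library labelled si-Eos from Treg. Genes of other kinds were dimmer in both hairpin libraries too. Lgr4 had 1555 in naive T cells, 2532 in Treg, 177 in the library labelled si-Eos and 14.9 in the library labelled si-RL. Duox2 had 2003, 3193, 399 and 27.3 in the same order. For Cisd3 and Igkv14-111, log2 differences of -6.46 and -6.40 between the library labelled si-RL and Treg stood beside -0.02 and -0.01 on a second probe. The NK and CD8 T cell marker Nkg7 had 16147 in the library labelled si-Eos and 256 in the library labelled si-RL. Only 6 of the 15 listed markers were measured in both hairpin libraries, so their median difference of 0.35, inside the middle 95% of random lists, left out markers seen in 1 library alone. Gzmd, a granzyme gene, was higher than in Treg in the library labelled si-Eos by 6.27 ± 0.22.

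Vegfa, Pdk1 and P4ha2 were unequal between the hairpin libraries, although both had been kept for the same time and 15 of 18 glycolysis genes differed between them by under 2-fold. Vegfa had a signal of 644 in the library labelled si-Eos and 2710 in the library labelled si-RL, against 54.7 and 56.0 in naive T cells and Treg. Pdk1 had 251 and 2599, against 425 and 277. P4ha2, a collagen prolyl hydroxylase, had 182 in the library labelled si-Eos and 4194 in the library labelled si-RL, a 28.1-fold difference. It had 120 in naive T cells and was not well above background in Treg. Against Treg, it was at least 560-fold higher in the library labelled si-RL. Hk2, by contrast, had 5229 and 4046 in the hairpin libraries, and Tpi1 had 14700 and 14200.

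Insulin probes were bright in the library labelled si-Eos alone: the Ins2 probe used had a signal of 5538, against 26.6 in naive T cells, 30.9 in Treg and 24.6 in the library labelled si-RL. A single-spot artefact is argued against, since the lowest difference of the 3 insulin probes was 6.19. Islet cells in the library have little for them. Iapp had 58.7 there against 61.5 in naive T cells and 67.8 in Treg, and Gcg had 12.6. The values of Iapp and Gcg had been seen before the test, so both lay outside it. Slc2a2 and Pcsk2 differed between the hairpin libraries by -1.09 and -0.27. In the library labelled si-Eos, 11 of 20 markers, including Ttr and Chgb, were not well above background, and the cells had been sorted. Cpe (3.06) and Pcsk1 (at least 2.28) went with islet cells. The median of 9 markers lay between 0.58 and 1.08, around the bound of 1, so the test did not decide. The range arises because 3 of the 9 were not above background in the library labelled si-RL. Those 3 counted through the library labelled si-Eos alone, which lifts the median. Islet cells are therefore not excluded, as no islet array gives the levels that their share would bring, and whether the probes detected insulin mRNA or another transcript was not analysed here.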
